A study of Caenorhabditis elegans with 3 samples.

How the data were processed

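The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of DRAP-1 in Caenorhabditis elegans. The worms were strain OP700, which carries a transgene that expresses DRAP-1 with a C-terminal GFP and FLAG tag, per the labels. The sample descriptions give an antibody against GFP for the precipitation, while the antibody label names drap-1, and the descriptions were followed here. The material was mixed-stage embryos of both sexes from bleached eggs, with an age of 3 hours in the labels, and chromatin was sheared by sonication. The 3 samples are biological replicates of 1 group and carry the replicate numbers 2, 3 and 4 in the labels. No comparison group is among the samples analysed here, so the comparisons are between replicates, between strong and weak regions, and between classes of genes and sequences.

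The values are the authors' own. Per the README texts deposited with the samples, each replicate has a list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure, which keeps regions whose ranks repeat between replicates. Each such list was derived from that replicate's alignment and 2 control files, a pooled list was derived from the alignments of the 3 replicates together, and a final IDR-thresholded list was derived from the replicate and pooled lists. All 5 lists are on genome build ce11, per the deposited README texts. The peak caller, its version, the IDR threshold and the kind of control are not given in the sources used here. Each of the 4 candidate lists holds 30000 regions and the IDR list holds 1468 peaks. Every region has a deposited signal value, whose scale is not stated, and a −log10 q-value, as the authors' caller gave them. The signal was used only to rank regions within a list, because the lists are not on a common scale, and the q-value was not used for filtering. The p-value column of the deposited lists holds a constant placeholder and was not used. All 1468 IDR peaks are the 1468 highest-signal regions of the pooled list, so that list was thresholded on signal in effect. Read depth is unknown, since the lists hold no read counts, and intervals given for shares cover only the counting of peaks or genes.

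Peaks were called per replicate and on pooled reads, so the replicate lists were compared at equal length, taking the N highest-signal regions of each, with N equal to 1468. A region counted as shared when its summit lay within 100 bp of a summit in the other list. Chance recovery was estimated from 100 random circular shifts of the IDR summits along their chromosomes (one-sided permutation p). Coordinates are 1-based. Gene 5′ ends came from the Ensembl release 115 gene models of WBcel235, the assembly that ce11 names, and all regions lay within its chromosome lengths. Symbols and products came from RefSeq, paired by WormBase identifier for 46881 of 46890 genes on 6 chromosomes. A summit within 500 bp of a gene 5′ end was called a promoter peak. The 1468 lowest-signal regions of the pooled list served as the control set, because the same caller found them in the same libraries.

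Shares were compared with Fisher's exact test, two-sided, and given with exact Clopper-Pearson 95% intervals. Medians of signal were compared with a two-sided permutation test with 100000 resamples, and intervals of medians came from 10000 bootstrap resamples. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. The 22 gene lists and 10 consensus sequences were fixed before the data were examined. A gene was tested if any of the 30000 pooled candidate summits lay within 500 bp of its 5′ end, against the other protein-coding genes so found, or all genes for lists of noncoding genes, and was called bound if an IDR summit did. Consensus sequences were sought on both strands within 50 bp of the summits of promoter peaks and of as many lowest-signal promoter candidates. The classes of the nearest gene, the tests of tRNA pseudogenes and the positions in exons and introns were added after seeing the data.

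The named peaks were chosen by a rule fixed before the data were examined. It takes the 25 highest-signal promoter peaks found among the N highest regions of every replicate, up to 4 members of each list past the threshold and up to 2 of each other list, the 5 highest peaks away from 5′ ends, drap-1 as the tagged gene and unc-119 as the rescue marker of the transgene.

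Alternatives covered the sharing distance, the number of regions per replicate, the promoter window, the set of 5′ ends, the control set, the background of the gene lists, the assignment of a peak to its nearest gene only, the higher-signal part of the IDR list and leaving out each replicate. For results drawn from the IDR list, the last kept the IDR peaks found among the N highest regions of both other replicates (827, 744 and 767 peaks with replicate 2, 3 or 4 not consulted). The reads of that replicate remain in the pooled calls, so these settings are filters on repeatability and do not remove a library. The tests were checked on simulated data. In 50 simulations on 46890 genes, a list bound at 4 times the usual rate was called in 50 for ribosomal protein genes, 50 for tRNA genes and 40 for neuron genes, and 5 of 950 tests of lists with no planted change were called. Each gene was bound independently in these simulations, so they do not cover genes that share a peak. A simulated replicate that shared 60% of 1468 summits gave a recovery of 59.9%. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and bedtools 2.31.1.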

Results

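DRAP-1 is the worm member of the DR1-associated protein 1 family, the alpha subunit of negative cofactor 2, which binds the TATA-binding protein at promoters. Its positions along the genome were measured by ChIP-seq of the GFP-tagged protein in mixed-stage embryos, in 3 biological replicates of 1 group. The data were 30000 candidate regions per replicate, 30000 from the pooled reads and 1468 IDR peaks, with no read counts, so the depth is unknown. The IDR peaks had signal values of 126.7 to 2257 with a median of 174.1, and a median width of 424 bp. Coordinates are those of ce11.

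The first comparison asked how well the replicates gave the same peaks. The peak with the highest signal, just upstream of the small nucleolar RNA (snoRNA) gene T06C12.16, ranked 1 in all 3 replicates, and those at the snoRNA genes Y43F8C.22 and W03C9.9 ranked 2 and 3 in all of them. Of the 1468 IDR peaks, 631 (43.0%, 95% interval 40.4 to 45.6) were found among the 1468 highest-signal regions of every replicate, 445 in 2 replicates, 331 in 1 and 61 in none. Randomly shifted peaks gave a mean of 0.117% and at most 0.341% (permutation p = 0.0099, the smallest that 100 shifts can give). Recovery fell with rank, from 99 of the 100 strongest peaks to 6 of the 468 peaks ranked below 1000. The replicate lists were cut at the length of the IDR list, so weak IDR peaks lie near each cut. Part of the fall follows from that cut. With 2 times N regions per replicate, 62.6% of the IDR peaks were found in every replicate. Replicates 2, 3 and 4 alone held 69.4%, 73.5% and 69.2% of the IDR peaks among their 1468 highest regions, and 95.5%, 96.6% and 94.0% among all 30000. The overlap of the 1468 highest regions was 52.8% between replicates 2 and 3, 51.3% between 2 and 4 and 59.7% between 3 and 4, with a mean of 54.6% ± 4.47 (SD over 3 pairs). Because the pooled list that gave the IDR peaks includes the same reads, these shares describe repeatability and are not independent tests of each peak.

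**Figure D1:**
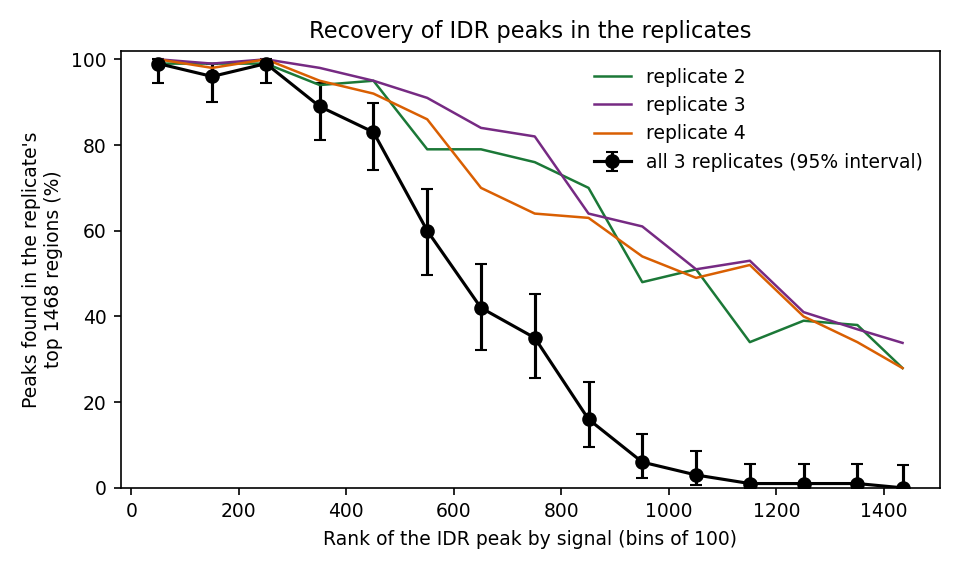
Share of IDR peaks found within 100 bp of a summit among the 1468 highest-signal regions of each replicate (coloured lines) and of all 3 replicates (black points with exact 95% intervals), in bins of 100 peaks ordered by signal on the horizontal axis. Of the first 100 peaks, 99 were in all 3 replicates, and of the last 68 none was, although 27.9% to 33.8% of those were found in each replicate by itself. The replicate lists end at the same rank as the IDR list, so part of the fall follows from the cut.

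The next comparison asked where in the genome the peaks lie. DRAP-1 peaks were concentrated at gene 5′ ends, where 1052 of 1468 (71.7%, 95% interval 69.3 to 74.0) had their summit within 500 bp, against 413 (28.1%) of the 1468 lowest-signal candidates (odds ratio 6.46, Fisher's exact p = 1.0e-126). The share was 66.8%, 68.5% and 68.3% for the highest regions of replicates 2, 3 and 4, a mean of 67.9% ± 0.969 (SD, n = 3), against 31.1% ± 1.26 for their lowest regions. The replicate ranges did not overlap, and 3 values against 3 cannot go below an exact permutation p of 0.1. Summits lay outside coding genes for 967 peaks (65.9%) against 382 of the low-signal regions, and in exons for 7.08% against 42.8% (629 regions), while introns held 397 and 457. The share in exons was lower (adjusted exact p = 5.5e-119), the share in introns slightly lower (odds ratio 0.82, adjusted exact p = 0.0198) and the share outside coding genes higher (adjusted exact p = 3.2e-106). Away from 5′ ends the intron shares were 35.3% and 33.6% (adjusted exact p = 0.541). At protein-coding genes the summits were mostly upstream, with a median offset of −174 bp from the nearest coding 5′ end (bootstrap 95% interval −187 to −161) and 84.5% of 599 peaks upstream. These are distances from annotated gene 5′ ends, which need not be the sites where transcription starts. Promoter peaks were also stronger than other peaks, with a median signal of 185.8 against 159.6, a difference of 26.2 (permutation p = 2e-05, the smallest that 100000 resamples can give). The median was 371.3 at peaks nearest snoRNA genes and 278.0 at those nearest tRNA genes. At the 465 peaks nearest protein-coding genes it was 167.4, close to that of other peaks, so the difference does not describe coding promoters alone. The per-replicate promoter share depends on the set of 5′ ends, and was 37.8% when only protein-coding genes were used.

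Genes for short noncoding RNAs carried the strongest peaks. For 185 IDR peaks (12.6%, 95% interval 10.9 to 14.4) the nearest 5′ end was that of a tRNA gene, against 6 of the low-signal regions (odds ratio 35.1, adjusted exact p = 5.5e-49). A further 69 peaks (4.70%, 95% interval 3.68 to 5.91) were nearest a snoRNA gene, against 3 (odds ratio 24.1, adjusted exact p = 2.8e-17, both Fisher's exact test). In the 3 replicates the tRNA share was 12.6% ± 0.961 and the snoRNA share 4.77% ± 0.204 (SD, n = 3), against 0.454% ± 0.142 and 0.363% ± 0.171 of their lowest-signal regions. Both shares were higher among repeatable peaks, at 22.7% and 8.24% of those found in every replicate, and at 18.9% to 20.03% and 7.04% to 7.39% of those found in both members of a pair of replicates. Of the 50 strongest IDR peaks, 22 were nearest a snoRNA gene, 13 a tRNA gene and 4 a protein-coding gene. The median signal was 371.3 at snoRNA genes, 278.0 at tRNA genes, 212.6 at the 15 peaks of small nuclear RNA (snRNA) genes and 167.4 at the 465 peaks of protein-coding genes. Among the highest regions of every replicate were 143 of the 185 tRNA peaks (77.3%) and 52 of the 69 snoRNA peaks (75.4%), against 189 of 465 peaks (40.6%) at protein-coding genes. Recovery falls with signal rank, so these recovery shares and the higher shares among repeatable peaks follow at least in part from the signal. They are not separate support for the excess at these genes. Unclassified noncoding RNA genes were nearest for 288 peaks against 89 low-signal regions (odds ratio 3.78, adjusted exact p = 1.8e-28), microRNA genes for 13 against 0 and snRNA genes for 15 against 0. Pseudogenes were nearest for 5 peaks against 21.

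**Figure D2:**
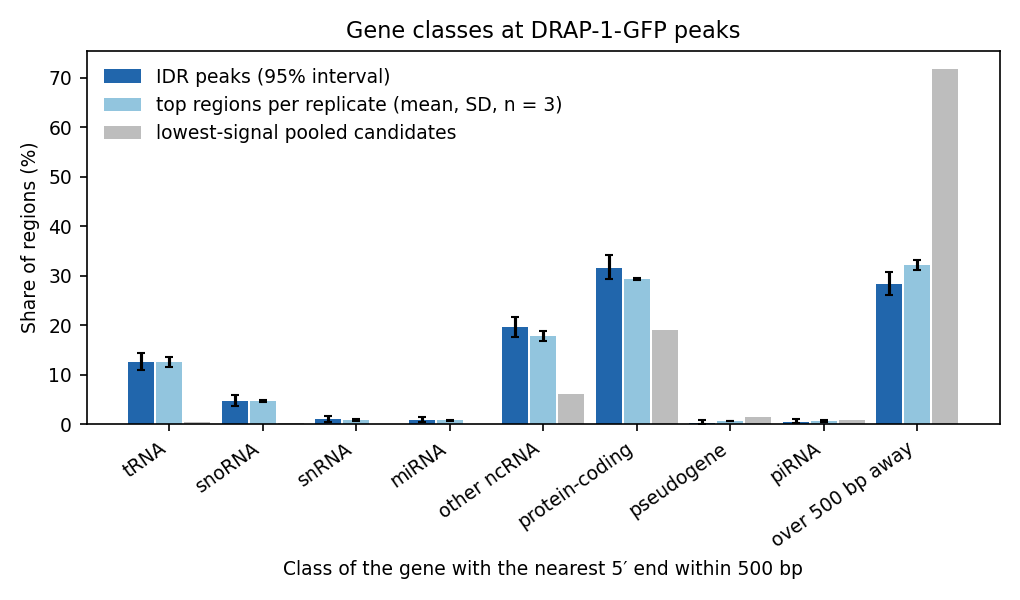
Percent of regions (vertical axis) by the class of the gene whose 5′ end is nearest within 500 bp (horizontal axis), for the 1468 IDR peaks with exact 95% intervals, the 1468 highest-signal regions per replicate as mean and SD of 3, and the 1468 lowest-signal pooled candidates. tRNA genes hold 12.6% of IDR peaks and 0.409% of the low-signal regions, and 28.3% of IDR peaks lie over 500 bp from any 5′ end, against 71.9% of the low-signal regions.

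The position of the summit differed between these classes. At tRNA genes the median summit lay 10 bp inside the gene (bootstrap 95% interval 8 to 13), at snoRNA genes at −48 bp (−53 to −40) and at protein-coding genes at −164 bp (−181 to −150), so that none of the intervals overlapped. Annotated 5′ ends may mark the start of transcription to a different degree in each class, and the offsets carry that limit. Within 100 bp of the 5′ end, 207 of 612 tRNA genes (33.8%, 95% interval 30.1 to 37.7) had an IDR summit, and 4 of 209 tRNA pseudogenes did (1.91%, 0.524 to 4.83), an odds ratio of 26.2 (Fisher's adjusted exact p = 2.2e-24). So did 67 of 346 snoRNA genes (19.4%, 15.3 to 23.9) and 15 of 129 snRNA genes (11.6%). None of 20 ribosomal RNA genes did, but only 1 of them had any pooled candidate there, and these repeated genes could hardly be tested. A pooled candidate lay there for 349 of the 612 tRNA genes and only 37 of the 209 tRNA pseudogenes. Part of the contrast with pseudogenes therefore lies in which genes had a candidate at all. No amino acid group of tRNA genes differed from the other tRNA genes, with 16 of 34 tRNA-Ala genes bound (47.1%) against 191 of 578 (33.0%; adjusted exact p = 0.820). snoRNA genes outside coding genes were bound in 31 of 130 cases and those inside a coding gene in 36 of 216, a difference that did not pass the threshold (adjusted exact p = 0.820). Many tRNA genes have near-identical copies, so reads may be split or shared among them and the peak of a given copy is uncertain.

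**Figure D3:**
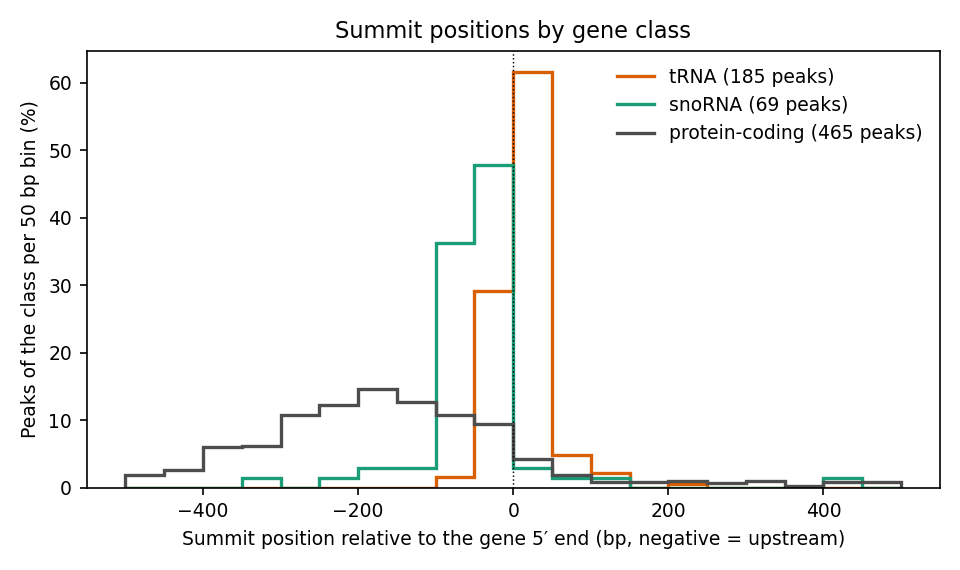
Distribution of IDR summits around gene 5′ ends, as the percent of a class's peaks per 50 bp bin (vertical axis) against the position relative to the 5′ end in bp (horizontal axis, negative is upstream), for peaks nearest tRNA, snoRNA and protein-coding genes. The bin from 0 to 50 bp holds 61.6% of the 185 tRNA peaks, the bin from −50 to 0 holds 47.8% of the 69 snoRNA peaks, and the 465 protein-coding peaks spread upstream with at most 14.6% in a bin.

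The strongest recovered promoter peak, at V from 15873735 to 15874202 with a signal of 2257, had its summit 49 bp upstream of T06C12.16, which lies on the minus strand outside coding genes. Y43F8C.22 had the next peak (V, 19642972 to 19643458, signal 1845) in an intron of Y43F8C.7, with the summit at −49 bp, and W03C9.9 the one after (II, 11960629 to 11961076, signal 1530) at −60 bp. The peak at C51F7.4 (V, 12303398 to 12303841, signal 1387) lay in an intron of frm-7 and 69 bp upstream of a neighbouring snoRNA gene, C51F7.3. Of the 25 peaks named by the rule, the snoRNA genes T03F7.8, ZK265.10, ZK994.7, T02E1.9, Y75B12B.12, C04G6.12, F55A11.10, C27H5.9, B0334.12 and H09I01.2 held signals from 1116 down to 670.4. The strongest tRNA gene was C04A11.t1, a leucine tRNA gene on X (13665379 to 13665811, signal 955.4, summit 12 bp inside the gene), with ranks of 10, 8 and 10 in replicates 2, 3 and 4. It was followed by F28F8.t3 for aspartate (signal 760.0), F17H10.t1 for glycine (758.1), C37A2.t1 for cysteine in an intron of cye-1 (744.6), W03G11.t1 for lysine (682.1) and F57F5.t1 for isoleucine (681.7). Unclassified noncoding RNA genes were F36H1.17 (895.6) and C14F11.14 (776.1). The 3 protein-coding genes were rpl-3, a large-subunit ribosomal protein gene (III, 3867418 to 3867754, signal 882.5, summit at −268 bp), tasp-1, a taspase homologue (III, signal 821.8, −61 bp), and atx-2, an ataxin-2 homologue (III, signal 766.3, −59 bp). All 3 ranked at or above 22 in every replicate.

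Away from 5′ ends the strongest peak lay on III from 8043784 to 8044154 (signal 1331, rank 5 in the IDR list and 5, 5 and 4 in the replicates), outside coding genes and at −524 bp from the 5′ end of K12H4.5. Of the other 4, 3 were on X. They lay from 11093975 to 11094384 between genes (signal 645.5), from 6296344 to 6296762 in an intron of mom-1 (619.3) and from 14525719 to 14526077 at −712 bp from nspc-17 (549.4). The last was on V from 17951298 to 17951559, at −525 bp from Y59A8B.24 (549.3).

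Gene lists fixed beforehand were compared with the other genes that had a candidate region, to ask which groups of genes are bound. Of 22 lists, 10 passed the threshold, 9 of them bound more often and 1 less often, and 12 lists had an unadjusted p under 0.05 (Fisher's exact test with Benjamini-Hochberg adjustment throughout). tRNA genes had the smallest p, with 240 of 451 bound (53.2%, 95% interval 48.5 to 57.9) against 13.2% of other genes (odds ratio 7.45, adjusted exact p = 5.2e-84), and snoRNA genes the next, with 85 of 194 (43.8%, odds ratio 4.68, adjusted exact p = 1.1e-21). Among protein-coding groups, bound genes made up 41.0% of ribosomal protein genes (32 of 78, 95% interval 30.0 to 52.7, odds ratio 5.30, adjusted exact p = 4.3e-10), against 11.6% of other coding genes. With each peak given to its nearest gene this odds ratio was 2.81, and with all annotated coding genes as background 16.5. The products of these genes build the cytosolic ribosome, and rpl-3 (signal 882.5), rpl-35 (526.0), rpl-18A (458.1) and rpl-15 (455.1) had the strongest peaks, at −268 to −455 bp. Translation factor genes were bound in 11 of 25 cases (44.0%, odds ratio 5.85, adjusted exact p = 0.000225), led by iff-2 (signal 451.0), which encodes initiation factor 5A, eif-3.C (419.5), eef-1A.2 (230.3) and eef-1A.1 (228.8). The peaks of eef-1A.2, eef-1A.1 and rpl-18A are nearer to another gene (R03G5.8, mir-5549 and Y17G9B.5).

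Histone genes were bound in 13 of 26 cases (95% interval 29.9 to 70.1, odds ratio 7.46, adjusted exact p = 1.1e-05). These 13 genes shared 8 peaks, since histone genes often lie in divergent pairs, such as his-67 and his-68 around 1 peak on I (signal 370.5) and his-3 and his-4 around 1 on V (285.3). Respiratory chain genes were bound in 8 of 20 cases (40.0%, odds ratio 4.94, adjusted exact p = 0.0038), among them cox-5B (signal 379.3), cox-5A (236.1), nuo-2 (226.0) and atp-1 (210.6). This call was lost, with a similar odds ratio of 4.36 and an adjusted exact p of 0.052, when only the 631 peaks found in every replicate were used, and with those found in both replicates 2 and 4 (odds ratio 3.59, adjusted exact p = 0.0836). snRNA genes were bound in 17 of 48 cases (35.4%, odds ratio 3.18, adjusted exact p = 0.000982), with W05B2.8 (signal 687.6), sls-2.4 (532.6), sls-2.1 (450.9) and sls-2.2 (365.8) highest. The W05B2.8 peak has no summit within 100 bp in replicate 2, where the strongest overlapping region ranks 44 with its summit 130 bp away. The sls-2.2 peak is nearest the noncoding RNA gene C17C3.23 and ranks 1148 in replicate 4. With the 744 peaks found in both replicates 2 and 4 the snRNA call was lost (odds ratio 2.37, adjusted exact p = 0.0836). The sls genes encode the leaders that are trans-spliced onto messenger RNAs, and as a list of their own 5 of 12 were bound (41.7%, adjusted exact p = 0.0495), with sls-2.9 (253.2) as the next member. The sls genes belong to the snRNA list too, the sls-2.9 peak is nearest a tRNA gene, and the call was lost when each peak was given to its nearest gene (odds ratio 3.46 against 4.13, adjusted exact p = 0.180). The call was also lost at 250 bp (adjusted exact p = 0.082) and without piRNA genes (adjusted exact p = 0.0547). With peaks found in every replicate the odds ratio was 8.37 (adjusted exact p = 0.0066), and with those found in pairs of replicates 6.77 to 7.34.

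Of 8 testable heat shock protein genes 7 were bound (87.5%, 95% interval 47.3 to 99.7, odds ratio 51.9, adjusted exact p = 1.1e-05), through 6 peaks. The highest were at hsp-1 (signal 344.9) and hsp-3 (326.5), which encode chaperones of the HSP70 family, followed by hsp-110 (162.5) and hsp-16.20 (137.0), and 3 of these 4 peaks are nearer to a noncoding RNA gene. With each peak given to its nearest gene the odds ratio was 4.21 (adjusted exact p = 0.207), and with peaks found in every replicate it was 5.78 (adjusted exact p = 0.148). With those found in both replicates 3 and 4 or both 2 and 3 it was 4.50 or 4.78 (adjusted exact p = 0.223 and 0.203). The call was kept with those found in both 2 and 4 (odds ratio 8.62, adjusted exact p = 0.0383) and lost in the higher-signal part (5.11, adjusted exact p = 0.1815). In replicate 2 the hsp-16.20 peak has an overlapping region with its summit 108 bp away. Cuticle collagen genes, the structural genes of the epidermis, were bound in 1 of 53 cases (1.89%, odds ratio 0.140, adjusted exact p = 0.0428), and that peak, at col-85 (signal 514.1), lies nearest a tRNA gene. The call for collagen genes was lost with peaks found in every replicate (odds ratio 0.330, adjusted exact p = 0.673) and with those found in both members of a pair of replicates (0.257 to 0.273).

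The other 12 lists did not pass. microRNA genes had 24 of 108 bound (22.2%, adjusted exact p = 0.0726), with mir-51 (signal 895.6) and mir-52 (634.6) highest, the mir-51 peak being that of F36H1.17. This list passed with a window of 1000 bp (odds ratio 1.74, adjusted exact p = 0.018) and with all annotated genes as background (2.70, adjusted exact p = 8.1e-05). It also passed without peaks near tRNA, snoRNA and snRNA genes (2.52, adjusted exact p = 0.0012), where the bound comparison genes fell from 1709 to 1071 by construction. Under the other alternatives adjusted p reached 0.925. Chemoreceptor genes of sensory neurons had 7 of 122 bound (5.74%, adjusted exact p = 0.0667), led by srh-269 (271.5), whose peak is nearest a tRNA gene, and srh-16 (252.5). Only 122 of 1311 annotated chemoreceptor genes were tested. The list passed with all annotated genes as background (odds ratio 0.130, adjusted exact p = 1.3e-13) and with a window of 1000 bp (0.397, adjusted exact p = 0.0018). It also passed without peaks near tRNA, snoRNA and snRNA genes (5 of 122 bound, odds ratio 0.347, adjusted exact p = 0.0259), and under the other alternatives adjusted p reached 0.707. Proteasome genes had 5 of 23, with rpn-7 (236.1) and rpn-11 (182.9), RNA polymerase II machinery genes 5 of 29, with mdt-9 (245.8) and mdt-26 (228.4), and cell cycle genes 4 of 16, with wee-1.3 (171.6) and pcn-1 (158.1). Muscle genes had 3 of 18, with unc-112 (415.4) and act-4 (158.9), intestine genes 1 of 6, asp-1 (145.9), and nuclear hormone receptor genes 5 of 72, with nhr-47 (231.6) and nhr-142 (229.4). The peaks of rpn-7, mdt-9, wee-1.3, nhr-47 and nhr-142 are nearer to another gene. Those of pcn-1 in replicate 2 and asp-1 in replicate 3 have no summit within 100 bp, only an overlapping region. No gene was bound among 15 embryonic lineage factor genes, 13 neuron genes, 11 germline genes and 3 major sperm protein genes, which leaves upper 95% limits of 21.8%, 24.7%, 28.5% and 70.8%.

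**Figure D4:**
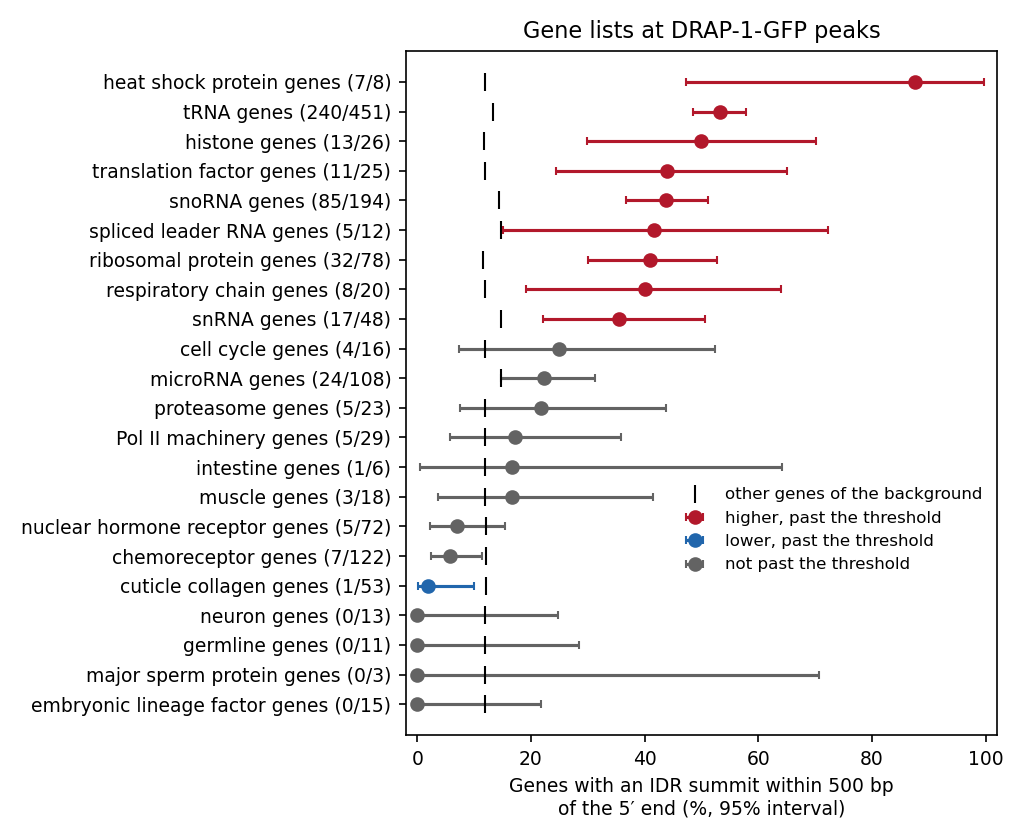
Percent of testable genes with an IDR summit within 500 bp of the 5′ end (horizontal axis) for the 22 gene lists (vertical axis, with bound and tested genes), as points with exact 95% intervals, beside the share among the other genes of the same background (vertical ticks). Lists past the threshold lie between 35.4% and 87.5% on the higher side and at 1.89% on the lower side, against 11.6% to 14.8% of other genes.

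Sequences near promoter summits were compared between the 1052 promoter peaks and 1052 lowest-signal promoter candidates. The pair of CpG dinucleotides CGCG was within 50 bp of 46.1% of promoter summits and 14.8% of control summits (odds ratio 4.91, adjusted exact p = 2.4e-55), the GAGA repeat of 20.8% and 8.27% (odds ratio 2.92, adjusted exact p = 7.2e-16) and the GC box of 9.41% and 3.04% (odds ratio 3.31, adjusted exact p = 2.4e-09). The B box, the internal promoter element of tRNA genes, was near 106 peaks (10.1%) and 3 controls (0.285%), an odds ratio of 39.2 (adjusted exact p = 2.4e-28). tRNA genes were nearest for 185 IDR peaks, with a median summit 10 bp inside the gene, and for 6 of the low-signal regions. The B box contrast therefore cannot be separated here from the excess of tRNA genes among the peaks. The TATA box was less frequent at peaks, at 4.85% against 8.75% (odds ratio 0.532, adjusted exact p = 0.000704), as were runs of T (158 and 281 regions, adjusted exact p = 1.2e-10), the CCAAT box (14.3% and 20.2%, adjusted exact p = 0.000564) and the GATA site (2.47% and 4.18%, adjusted exact p = 0.0476). The windows lay around summits, which at coding genes had a median offset of −174 bp, so these shares do not describe the 5′ ends themselves. Peaks and controls were also not matched for gene class or base composition. The GC-rich CGCG and GC box were higher at peaks, and the AT-rich TATA box and runs of T were lower. These contrasts therefore cannot be told apart from a difference in base composition, which was not tested. With flanks of the same peaks as control the TATA odds ratio was 0.354 (adjusted exact p = 1.1e-12). The E-box (2.19% and 3.23%, adjusted exact p = 0.179) and the E2F-like site (1.24% and 0.475%, adjusted exact p = 0.105) did not pass, so 8 of 10 did, all by Fisher's exact test. The run of T lost its call with a window of 100 bp (odds ratio 0.846, adjusted exact p = 0.0804), and the CCAAT box in the higher-signal part of the peaks (odds ratio 0.725, adjusted exact p = 0.0512). Over the alternatives the odds ratio ran from 18.02 to 53.03 for the B box and from 2.98 to 7.70 for the GC box. Of these, the lower B box value and the higher GC box value came with flanks of the same peaks as control.

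The X chromosome held more peaks than any autosome, 353 of 1468 (24.0%) or 19.9 per Mb, against 10.3 per Mb on IV to 16.8 per Mb on III. It held 16.9% of the pooled candidates. Protein-coding genes with a candidate region were bound in 108 of 860 cases on X (12.6%) and in 640 of 5387 on autosomes (11.9%), which did not differ detectably (odds ratio 1.07, Fisher's exact p = 0.572). With a promoter window of 1000 bp the odds ratio was 1.25 (exact p = 0.0177). tRNA genes, of which 276 of 612 are on X, had a summit within 100 bp of the 5′ end in 33.7% of cases on X and 33.9% on autosomes (odds ratio 0.990, adjusted exact p = 1).

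The tagged gene itself, drap-1 (V, 9730106 to 9734022), had no region within 500 bp of its 5′ end in the IDR list, the pooled list or any of the 3 replicate lists. The same was true of unc-119 (III, 10902641 to 10908935), the neuronal gene used as the rescue marker. The stretch without pooled candidates around drap-1 was 51705 bp long, with its limits at 9704558 and 9756263, and in replicates 2, 3 and 4 it was 49533, 42142 and 46516 bp. The pooled list held 0 regions within 20 kb of drap-1 and 17 within 20 kb of unc-119, against 11.8 and 16.7 at the mean density of each chromosome. Within 20 kb of drap-1 the lists of replicates 2 and 4 also held 0 regions, and that of replicate 3 held 2.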

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

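The removal of peaks near short RNA genes, the background without piRNA genes and all alternatives for the tRNA and snoRNA shares and for tRNA pseudogenes were chosen after seeing the data. Of 350 alternative values, 290 kept their direction and their side of the threshold or stayed within the spread, 13 moved, 10 newly passed the threshold, 21 no longer passed and 16 reversed, none of the 16 past the threshold before or after. Recovery in every replicate stayed above chance under all 9 alternatives run, at 26.98% to 79.0%. The promoter share of IDR peaks stayed above its control under all 6, at 40.8% to 79.4%. The lists of tRNA, snoRNA, ribosomal protein, translation factor and histone genes passed under every alternative run for them, with odds ratios of 7.25 to 19.4, 4.54 to 8.87, 2.81 to 16.5, 4.56 to 13.03 and 4.69 to 13.5. From 7 to 14 lists passed per alternative. The overlap between replicates was 41.7% at 50 bp and 59.7% at 200 bp, 63.9% with 734 regions per replicate, 42.3% with 2 times N, and 51.3% to 59.7% without 1 replicate. The promoter share per replicate was 55.6% at 250 bp, 76.5% at 1000 bp, 37.8% with coding 5′ ends only, 70.9% with the 5′ ends of every transcript, 77.7% with 734 regions and 56.9% with 2 times N. The windows of 250 and 1000 bp gave median offsets of −130 and −202 bp, since the window bounds the offset. They gave odds ratios for coding genes on X of 0.991, a reversal of a value that did not differ, and 1.25 (exact p from 0.0177 to 1 over the alternatives). With 250 bp the calls for spliced leader (odds ratio 3.67), respiratory chain (3.90) and cuticle collagen genes (0, no gene bound) were lost. Heat shock protein genes have no value listed at 250 bp, and the 350 values and the ranges here leave that setting out for them. With each peak given to its nearest gene, those for spliced leader (3.46), heat shock (4.21) and collagen genes (0) were lost, and without piRNA genes that for spliced leader genes (4.01). In the higher-signal part of the IDR list those for heat shock (5.11) and collagen genes (0.292) were lost, and with peaks found in every replicate those for respiratory chain (4.36), heat shock (5.78) and collagen genes (0.330). With peaks found in both members of a pair of replicates the odds ratio was 2.37 to 3.54 for snRNA genes and 3.59 to 4.80 for respiratory chain genes, both lost with replicates 2 and 4. It was 4.50 to 8.62 for heat shock genes, lost with 3 and 4 and with 2 and 3, and 0.257 to 0.273 for collagen genes, lost with each pair. These pair settings hold 744 to 827 peaks of a list that still includes the reads of the other replicate, so they test repeatability with fewer peaks and not the removal of a library, and otherwise the cause was not tested. Over the alternatives the adjusted exact p ran from 1.8e-05 to 0.0836 for snRNA, 3.8e-05 to 0.0836 for respiratory chain, 0.0066 to 0.180 for spliced leader, 3.6e-06 to 0.223 for heat shock and 0.0012 to 0.673 for collagen genes. The other changes were calls gained for microRNA and chemoreceptor genes (3 alternatives each: 1000 bp, all annotated genes as background, and peaks near short RNA genes removed, which by construction lowers the bound share of the genes compared with microRNA genes), proteasome genes, cell cycle genes and the E2F-like site (1 each), and calls lost for the run of T and the CCAAT box (1 each). The other 15 reversals were odds ratios for muscle genes (0.773 at 250 bp, 0.898 in the higher-signal part, 0.791 with replicates 3 and 4, 0.839 with 2 and 3), intestine genes (0.967 at 1000 bp, and 0 in the higher-signal part, with peaks found in every replicate and with each pair), cell cycle genes (0 in the higher-signal part, with peaks found in every replicate, with replicates 2 and 4 and with 2 and 3) and the E-box (1.12 with flanks as control). The remaining pair kept the direction for muscle genes (1.79 with replicates 2 and 4) and cell cycle genes (1.93 with 3 and 4). The cause of the reversals was not tested. What depth limits could not be assessed, since the lists hold no read counts.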

Other observations

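All sequences and tests in this part were chosen after the results they bear on were seen. On X, some of the strongest peaks away from 5′ ends lie at the core sequence TCGCGMAGGG (M is A or C) of the elements that recruit the dosage compensation complex, which lowers X expression in hermaphrodites. It lay within 150 bp of the summit in 10 of 106 such peaks on X, against 1 of 310 on autosomes (odds ratio 32.2, adjusted exact p = 7.2e-06) and 5 of 2978 other X candidates away from 5′ ends (odds ratio 61.9, adjusted exact p = 1.2e-11). Counted over the genome, 16 of 28 matches on X had an IDR summit within 150 bp (57.1%) and 1 of 29 on autosomes did (3.45%, odds ratio 37.3, exact p = 6.8e-06). Of the 10 peaks 2 overlap, and with overlapping regions counted once there were 9 on X, against 1 of 299 on autosomes (odds ratio 28.2, exact p = 3.0e-05) and 4 of 2664 other X candidates (exact p = 6.7e-11). The 10 peaks had a median signal of 443.1, and 9 of them were among the highest regions of every replicate. The strongest have summits at 11094215, 6296527 in an intron of mom-1, 14525893, 4209264 and 806690 on X.

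Other sequences marked groups of peaks. CACACACA lay within 50 bp of 48 of 416 summits away from 5′ ends and 2 of 416 low-signal regions (11.5% against 0.481%, adjusted exact p = 3.6e-12), and GAGACGCAG near 52 and 9 (odds ratio 6.46, adjusted exact p = 8.3e-09). At peaks nearest protein-coding genes, AAGTGCGC was near 37 of 465 summits against 2 of 465 (7.96% against 0.430%, adjusted exact p = 2.9e-09) and AAACGCGC near 33 against 4 (odds ratio 8.80, adjusted exact p = 8.2e-07). These words were found in the same peaks on which they were counted, so the exact p-values here describe and do not test. After removal of peaks near tRNA, snoRNA and snRNA genes, 256 of the 1147 left were on X (22.3%).

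The peaks at tRNA and snoRNA genes were weighed against 3 explanations. The values go against reads shared between near-identical copies as the whole cause, with limits. Of 64 tRNA genes with no copy of equal length within 3 mismatches, 12 were bound (18.8%, 95% interval 10.1 to 30.5) against 1.91% of tRNA pseudogenes (0.524 to 4.83). Copies of another length were not sought, so some of the 64 may have one. Only 37 of 209 tRNA pseudogenes had any pooled candidate within 100 bp of the 5′ end, against 349 of 612 tRNA genes. tRNA genes with an equal-length copy within 3 mismatches were bound more often (195 of 548, odds ratio 2.39, exact p = 0.0076), so shared reads may still add to their peaks. All 346 snoRNA genes lacked an identical copy among snoRNA genes, and 67 were bound (19.4%, 95% interval 15.3 to 23.9). This argues against identical copies as the source of the snoRNA peaks, but snoRNA copies with mismatches were not sought. Heavily transcribed genes may gather signal whatever the factor, and 41.0% of ribosomal protein genes were bound, which goes with it. Binding of DRAP-1 itself at these genes would give the same share. That explanation stays open, as no untagged control was analysed here. A candidate explanation is that DRAP-1 occupies RNA polymerase III promoters. A B box (GTTCRANNC) lay within 100 bp upstream of 25 of 67 bound snoRNA genes and 7 of 279 others (odds ratio 23.1, exact p = 2.7e-14). Most bound snoRNA genes lacked the box. Transcription was not measured here, so heavy transcription of the genes with a box could give the same contrast.

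The 353 IDR peaks on X (24.0%, against 16.6% of other candidates) exceed the 309 that the mix of nearest gene classes would give, so that mix may account for part. Within classes X held 45.4% of IDR peaks and 39.8% of other candidates at tRNA genes, 15.7% and 13.6% at coding genes, 29.9% and 33.1% at unclassified noncoding RNA genes and 2.90% and 10.3% at snoRNA genes, none past the threshold. Among regions away from 5′ ends X held 25.5% and 15.4% (odds ratio 1.87, adjusted exact p = 8.5e-07), which argues against the mix as the whole cause. Without peaks holding the recruitment core the odds ratio was still 1.71 (exact p = 1.6e-05), and without those holding the CA repeat 1.80 (exact p = 4.4e-06), so neither sequence accounts for all of it. Leaving out matches to the core kept 96 of the 106 X peaks away from 5′ ends. Recruitment elements of other sequence were not covered, so their part is not bounded here. No group in the design separates a biological cause, and what remains is open.

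The stretch without candidates around drap-1 was weighed against 2 explanations, with no biological one tested. A lack of promoters is argued against, since 16 coding 5′ ends lie in the pooled gap, against 12.3 at the density of the chromosome. Extra copies of drap-1 from the transgene, if also present in the control, could raise the control signal there. Pooled gaps with as many coding 5′ ends hold 7.01% of coding genes (3.71%, 3.76% and 1.55% in the lists of replicates 2, 3 and 4), so a gap of this kind is uncommon but not rare enough to decide, and this stays open.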
